A study of Nicotiana tabacum with 12 samples.

How the data were processed

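The measurements were libraries of parallel analysis of RNA ends (PARE), a degradome method that captures the 5′ ends of uncapped, polyadenylated RNA fragments carrying a 5′ monophosphate. Such fragments include the 3′ products of cuts that a miRNA guides Argonaute proteins to make, and intermediates of 5′-to-3′ decay. Per the labels, total RNA came from tobacco BY-2 suspension cells that were grown in the dark, expressed AGO1 fused to GFP, and were synchronized with aphidicolin, an inhibitor of replicative DNA polymerases. The labels put 12 libraries into 4 phases (S, G2, M and G1) with 3 replicates each. They do not say whether the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

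Each deposited file has 2 columns, a tag sequence of 18 to 20 nt and its count, and the values are whole-number counts per distinct tag that are not normalized. Per the submitters' processing notes, FastQC, Trimmomatic and Bowtie were used. Their versions, settings and roles, and the genome build, are not given in the sources used here. Whether tags had to match a tobacco sequence before deposit is likewise not given in the sources used here. Tags with an undetermined base (N) were left out, which removed at most 0.00187% of a library's tags.

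The samples, the main tests, the gene lists, the miRNA families, the rule for named tags and most alternatives were set before the data were examined. The design was to match tags to annotated transcripts and to test genes. No genome or transcript sequence was used here, and a table of names for 79372 tobacco genes holds no sequences, so the rows tested were the tags themselves, as that design allowed. Because tags carry no gene names, at most 2 tags that rose and 2 that fell are named per comparison: those with the largest log2 fold change among tags with an adjusted p under 0.05, a mean count of at least 20 over the 6 libraries, and all 3 libraries of one phase above all 3 of the other. Chance alone separates 3 libraries from 3 in 10% of tags. The share of cleavage tags among all tags of a target transcript, 5′ ends upstream of exon junctions, tags shared between genes, and shares of chloroplast, mitochondrial and antisense transcripts all need transcripts and were not analysed here.

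To give the tags a biological reading, 28 protein sequences, from single motifs to full-length proteins, were written from textbook knowledge of conserved plant proteins. This step was chosen after the data had been seen to come without a reference. A tag of 20 nt was matched to a protein when its 18 nt in one reading frame spelled 6 residues in a row of that protein. It was kept as linked when it overlapped, base for base and 1 to 5 nt apart, another tag matched at a different residue of the same protein. Of 38826241 distinct 20 nt tags searched, 164369 matched and 140627 were linked, holding 5935328 tags or 2.78% of all. Another 37 tags fitted more than 1 place and were left out. Such tags are described as tags that can encode a stretch of the protein. Paralogs that share the stretch are counted together, and pseudogenes or unrelated transcripts are not excluded.

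Each protein was shuffled 20 times and matched alike. A protein was used when more of its peptides had linked tags than in the highest of the 20 shuffles, which 27 of the 28 met; GFP did not. This rule was set after the values had been seen and replaced one on tag totals, under which 23 proteins pass; results under the earlier rule are among the alternatives. The tags of each protein were summed per library, and levels are given as CPM (counts scaled per library in the usual way, here over the TMM-scaled library size), as mean ± SD over 3 libraries. Library factors ran from 0.832 in S replicate 3 to 1.19 in G1 replicate 1. The proteins were assigned to the gene lists fixed earlier. Only core histones stood for the list of core and linker histones, since no linker histone was among the proteins. Ubiquitin, EF1A and GAPDH belong to no list, and no protein stood for RNA decay, auxin, the proteasome and APC/C, peroxidases and glutathione transferases, or defence, so these lists were not analysed here. The values of 1 protein and 1 cleavage tag that entered the tests and counts are not reported here.

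Tags kept by the default count filter of edgeR, 183819 in all, were tested with the quasi-likelihood F test of edgeR 4.0.16 over all 12 libraries with TMM factors. Benjamini-Hochberg adjustment over tags had a threshold of 0.05. Protein sums and miRNA cleavage tags were tested by the same model with the library factors of the tag table. The test over 4 phases was adjusted over the sums or cleavage tags, and the tests of successive phases were adjusted over these and the 4 comparisons together. The fold of a pair is the later phase over the earlier one in the order of the cycle, with S after G1. The order and times of sampling after aphidicolin were not used. Phases of a synchronized culture also differ in time since the drug, so an effect of phase cannot be told apart from one of that time. Sums were also compared over the 4 phases with an exact permutation test of the F statistic over all 15400 partitions of 12 libraries into 4 groups of 3, on log2 of CPM plus 0.01. The smallest p it can give is 6.49e-05, and it has no direction.

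Gene lists were tested with camera of limma 3.58.1 on voom-weighted values, with a preset inter-gene correlation of 0.01 and adjustment over lists and comparisons. Of 17 lists, 8 had tags that passed the filter. Because 1 list holds many tags of few transcripts, the p-value with a correlation estimated per list is given beside each call. A list's members are the tags of its proteins, and the count of members called is given over all tags tested and adjusted over the list alone.

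Cleavage sites of 27 families, all miRNAs except the trans-acting tasiR-ARF, were searched without transcripts. The small RNA sequences, like the proteins, were written from textbook knowledge and were not checked against a database. A site tag had to be complementary to the small RNA with a penalty of at most 4, where a mismatch cost 1 and a G:U pair 0.5, doubled at positions 2 to 13. A cleavage tag had to start opposite nucleotide 10, hold at least 10 tags over the 12 libraries, share its first 10 bases with the end of the site tag, and form with it a sequence of 30 nt across whose join at least 2 other tags lay. It also had to be the most frequent of the 11 possible starts in that sequence, in place of the most frequent of its transcript. Each small RNA sequence was shuffled 100 times for the background. The share of a family's cleavage tags was taken as CPM, which does not separate cleavage from transcript level.

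The bases of a codon at which linked tags started, tags 16 and 17 nt upstream of stop codons against those 20 to 50 nt upstream (12 proteins with a stop codon), and 5 library shares (5.8S and 18S rRNA, tags of 19 nt, the 10 most frequent tags, and tags seen once) were compared with the same exact permutation test.

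Alternatives were DESeq2 1.42.0, RLE factors, a replicate block, a stricter filter (mean of at least 10 tags), other miRNA settings, an estimated correlation, and leaving out each library in turn. Chosen after seeing the data were a looser filter (at least 4 tags in 3 libraries and 15 in all), no composition factor, joining tags by their first 18 nt, other ways of matching tags to proteins and choosing proteins, RLE factors for the sums and cleavage tags, DESeq2 for the sums, and leaving out 2 or 3 libraries that stood apart. No filter at all could not be fitted with 46753583 distinct tags. The labels do not say what a replicate number marks, so pairing was judged from the data, by the correlation of deviations from the phase means between libraries of the same number. It was above 0.1 for all 3 pairs of S and G2 (0.608, 0.394 and 0.729 for replicates 1, 2 and 3), of G1 and S (0.483, 0.130 and 0.284) and of G1 and G2 (0.501, 0.173 and 0.309), but not for all pairs with M. Reading this per comparison was decided after the calls had been seen. Scripts ran in R 4.3.3 and Python 3.11.15, and the edgeR test of tags and camera were first run on simulated data. The exact permutation test, DESeq2 and the fits of protein sums and cleavage tags were not. With 50 tags changed at each size among 10000 simulated, edgeR recovered 0% of 2-fold changes, 26% to 28% of 4-fold, 58% to 64% of 8-fold and 80% to 88% of 16-fold ones for successive phases. Counting limits for a value of 0 use 3 counts over the 3 libraries of a phase. They cover counting error only, since PCR copies are not independent molecules.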

Results

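The 12 PARE libraries sampled RNA 5′ ends in tobacco BY-2, a fast-dividing suspension line of Nicotiana tabacum, at 4 stages of a synchronized cell cycle. The cells carried AGO1, the main plant Argonaute of miRNA-guided RNA cleavage, as a fusion to GFP, and the title of the series asks how AGO1 is regulated and what it does through the cycle. Libraries held 14647449, 14718782 and 13837947 tags in S (replicates 1 to 3), 26026372, 16053389 and 14764419 in G2, 14549025, 14711471 and 19993529 in M, and 27917385, 19015853 and 16967469 in G1. Among 213199360 tags there were 46753583 distinct sequences, of which 63.0% occurred in 1 library only, whereas the 464988 sequences present in all 12 libraries made up 36.1% of the tags. At these depths, 0 tags in the 3 libraries of a phase allow a level of up to 0.0715 CPM in S, 0.0503 in G2, 0.0622 in M and 0.0443 in G1. A first principal component with 33.2% of the variance set the S libraries (scores of 156, 157 and 410) apart from those of M (−213, −200 and −211). The next component, with 27.7%, set G2 replicate 3 (−258) and S replicate 3 (−213) apart from the other libraries of their phases, which lay between 32.4 and 269. S replicate 3 also had the highest share of 19 nt tags, 15.8%, against 4.24% to 11.3% in the other libraries.

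**Figure D1:**
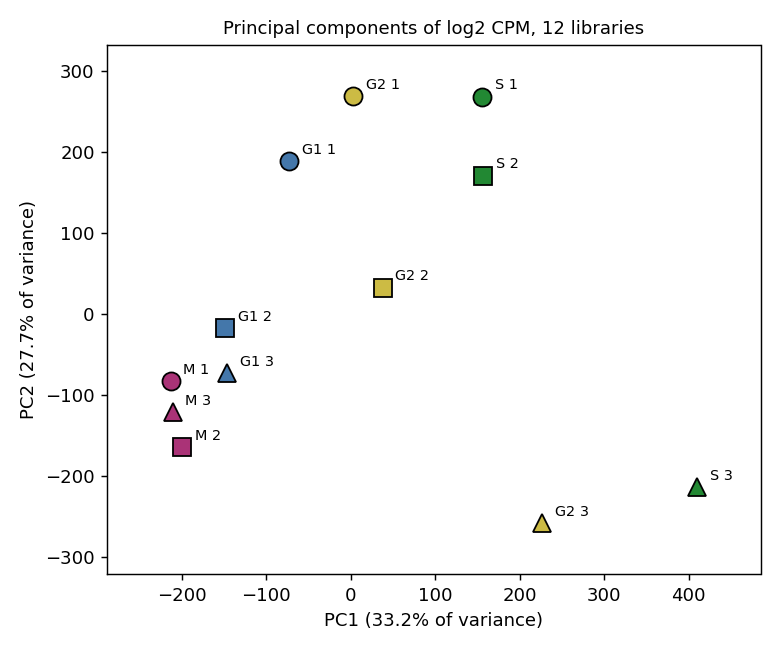
Scores of the 12 libraries on the first and next principal components of log2 CPM (33.2% and 27.7% of the variance), coloured by phase and marked by replicate. The 3 M libraries lie together at −213 to −200 on the first axis, and G2 replicate 3 and S replicate 3 lie apart at −258 and −213 on the other.

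Over the whole cycle, tags that can encode the core histones, which package newly replicated DNA, were most frequent in S and least frequent in M. Those of histone H4 fell from 5439 ± 1736 CPM in S through 2076 ± 772 in G2 to 262 ± 31.3 in M (SD, n = 3). Tags of B-type cyclin, the activating partner of mitotic kinases, peaked in M at 51.9 ± 5.77 CPM against 4.64 ± 1.24 in S. Those of B-type CDK, its plant-specific kinase, stayed between 108 ± 15.3 and 164 ± 7.90 CPM from S to M and stood at 26.9 ± 4.08 in G1. Tags of AGO1 PIWI domain, the slicer domain of AGO1, lay within 49.7 ± 6.01 CPM in G2 and 55.9 ± 4.95 in M. They were not called (edgeR adjusted p = 0.757, exact permutation p = 0.711). All libraries came from cells with the AGO1 fusion, so tags of the transgene and of the cells' own AGO1 cannot be told apart in this sum. In edgeR 20384 of 183819 tags differed between phases, as did the summed tags of 16 of 27 proteins, with adjusted p from 3.3e-07 for B-type CDK to 0.0168 for ubiquitin. The ubiquitin call ended under 5 of 21 alternatives, with an adjusted p of up to 0.119. Among these were the fits without G2 replicate 2 (edgeR adjusted p = 0.0972), G2 replicate 3 (0.0859) or a composition factor (0.115). Each sum covers all paralogs that share the stretch.

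The 11 sums not called over the 4 phases were, apart from AGO1 PIWI domain, those of A-type CDK, actin, EF1A, GAPDH, HSP70 and ribosomal protein S23, L23, L40, S29 and L41. With the replicate number as a block, 20 of 27 sums were called over the phases. HSP70 and ribosomal protein L23, L40 and S29 were each called under some alternative, so their lack of a call depends on the setting. A-type CDK, the kinase of both G1 and G2 control, stood at 20.5, 22.1, 25.5 and 20.3 CPM in S, G2, M and G1 (edgeR adjusted p = 0.428). EF1A, a translation elongation factor, stood at 4206, 4243, 4701 and 4328 CPM (edgeR adjusted p = 0.757). Actin, at 1196 CPM in S and 932 in G1, was not called by edgeR (adjusted p = 0.208) but passed the exact permutation test (adjusted p = 0.0312). Without G1 replicate 3 A-type CDK passed over the phases (edgeR adjusted p = 0.0151) and fell from M to G1 (−0.60 on the log2 scale; 0.00494).

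**Figure D2:**
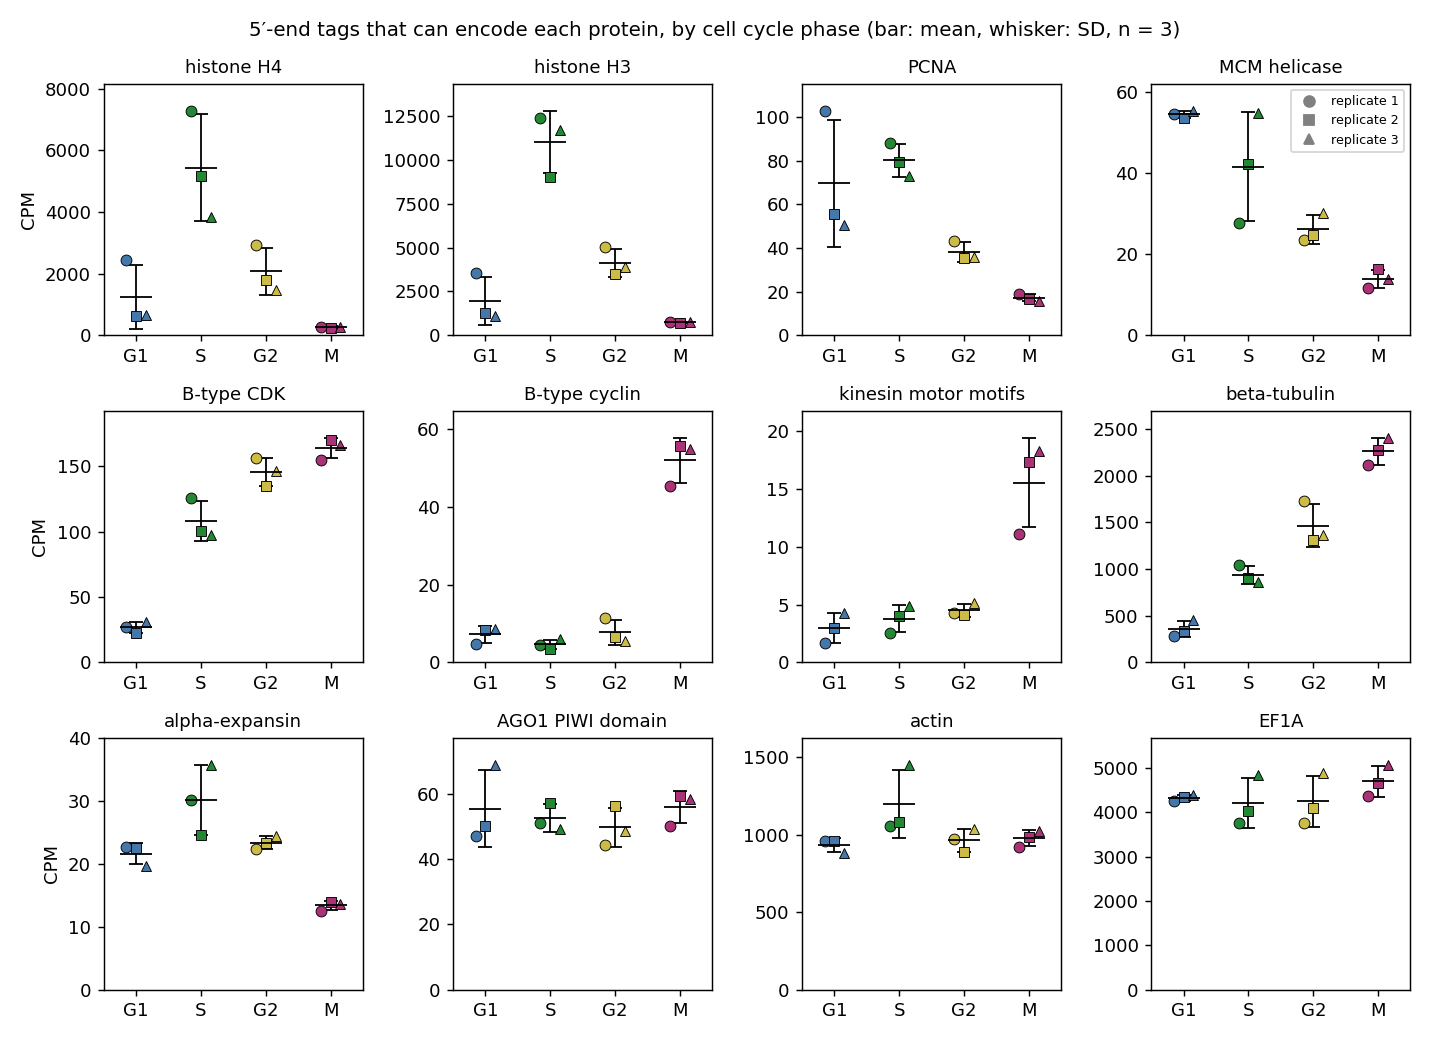
Summed tags that can encode a stretch of each of 12 proteins, in CPM, for the 3 libraries of G1, S, G2 and M (circle, square and triangle for replicates 1, 2 and 3), with a bar at the mean and whiskers of 1 SD. Histone H4 and histone H3 have their highest means in S (5439 and 11039 CPM), B-type cyclin in M (51.9), and B-type CDK and beta-tubulin their lowest in G1 (26.9 and 360).

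Between S and G2, which asks what changes as replication ends, tags of 3 core histones fell. Those of histone H3 were 2.68 times as frequent in S (11039 ± 1771 CPM) as in G2 (4123 ± 805; SD, n = 3), and those of histone H4 and histone H2A 2.62 and 2.21 times. Tags of PCNA, the sliding clamp of replicative DNA polymerases, went from 80.3 ± 7.55 to 38.1 ± 4.51 CPM, and those of MCM helicase, which unwinds replication origins, from 41.7 ± 13.5 to 26.2 ± 3.58. In the other direction, tags of B-type CDK rose 1.35-fold to 146 ± 10.7 CPM and those of beta-tubulin, a microtubule subunit, 1.57-fold to 1465 ± 228. edgeR called 9 of the 27 sums, 2 up and 7 down. Its adjusted p was 0.00744 for histone H3, 0.032 for histone H4, 0.0136 for histone H2A and 0.00293 for PCNA. For MCM helicase it was 0.0267, for B-type CDK 0.0342 and for beta-tubulin 0.0155, and the other calls were ubiquitin and chlorophyll a/b binding protein. Histone H2B, with a log2 change of −1.07 (edgeR adjusted p = 0.056), and B-type cyclin, with 0.77 (0.0736), were not called. With the replicate number as a block, histone H2B passed (log2 change −1.06; 0.00168), as did HSP70 (0.54; 0.0094), and 11 sums were called.

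The calls of histone H4, MCM helicase and B-type CDK between S and G2 each ended when any of several libraries was left out. For histone H4 these were G2 replicates 2 and 3 and S replicates 1 and 2 (edgeR adjusted p of 0.103, 0.114, 0.111 and 0.0638). For MCM helicase they were G2 replicates 1 and 2 and S replicates 2 and 3 (0.088, 0.0849, 0.0651 and 0.128). For B-type CDK they were G2 replicates 1 and 3, M replicates 2 and 3 and S replicates 2 and 3 (0.0956, 0.0838, 0.0539, 0.0564, 0.107 and 0.0966). Histone H2A was lost without G2 replicate 2 (0.0512) and beta-tubulin without G2 replicate 1 (0.0584). Without a composition factor, histone H4 (0.111), histone H2A (0.0784) and B-type CDK (0.0845) were not called. Without both G2 replicate 3 and S replicate 3, PCNA was still called, while histone H4 (0.116), histone H3 (0.0748), histone H2A (0.0864), MCM helicase (0.0898), B-type CDK (0.161) and beta-tubulin (0.0671) were not. Of the values not called, histone H2B passed without G1 replicate 1, 2 or 3 (0.00355, 0.0409 and 0.0482) or G2 replicate 1 (0.0372), and B-type cyclin without G1 replicate 1 (0.0347) or G2 replicate 3 (0.0372).

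Among single tags, edgeR called 66 between S and G2, of which 23 were higher in G2 and 43 lower, while 14250 had an unadjusted p under 0.05. GAAGCTGTTGAAGATGCGGA went from 0.114 ± 0.0623 CPM in S to 2.47 ± 0.574 in G2 (log2 change 4.31; edgeR adjusted p = 0.0309) and TTGCTGCAAGGATTCACAGG from 0.0851 ± 0.0936 to 2.15 ± 0.965 (4.41; 0.046). ACAACATATTTGTTCTTTTT went from 6.73 ± 4.79 to 0.113 ± 0.0444 CPM (−5.77; 0.0309) and ATCCACAACATATTTGTTC, which overlaps it, from 5.84 ± 6.09 to 0.0468 ± 0.0810 (−7.10; 0.0458). With the replicate number as a block the count was 3950, of which 785 were higher in G2 and 3165 lower. It was 32 without a composition factor, 16 higher and 16 lower. Without the block it changed when any single library was left out, also one of a phase not compared. A lower count thus does not show that the calls rested on the library left out. It was 0 without G1 replicate 2 or 3, G2 replicate 2 or 3, M replicate 1, 2 or 3, or S replicate 2. It was 8 without G1 replicate 1, 9 without S replicate 1, 37 without S replicate 3 and 225 without G2 replicate 1. In these fits 14712 to 24936 tags had an unadjusted p under 0.05.

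Taken as sets of tags, the core and linker histones (6973 tags, all of core histones) fell from S to G2, with a median log2 change of −1.29 (camera adjusted p = 5.4e-74 at the preset correlation), a call lost at adjusted p = 0.056 with an estimated correlation. Of these tags 4 fell by the test over all tags, and 2158 when adjusted over the list alone. Mitotic cyclins and B-type CDKs rose (55 tags, median 0.65; camera adjusted p = 1.64e-08, and 0.0314 with an estimated correlation) with 0 members called either way. The set of G1 cyclins and G1/S regulators also rose, but its 3 tags all belong to A-type CDK, whose sum was not called (median 2.08; camera adjusted p = 0.000544, and 0.0422 with an estimated correlation); 0 members were called over all tags and 3 rose adjusted over the list alone. Heat shock proteins and chaperones (930 tags, all of HSP70; median 0.32), tubulins and actins (3320 tags; 0.19) and cytosolic ribosomal proteins (1125 tags; 0.12) rose at the preset correlation. Their camera adjusted p was 2.04e-11, 5.62e-07 and 0.00319, and adjusted p = 0.17, 0.219 and 0.659 with an estimated correlation. The actin sum did not share the rise of its list, at 1196 CPM in S and 964 in G2 without a call. DNA replication (5 tags; −0.75) fell at camera adjusted p = 0.0279 and not with an estimated correlation (adjusted p = 0.219), with 1 member falling when adjusted over the list alone. The ribosomal call ended without G2 replicate 1 (0.737) or S replicate 3 (0.205), and that of DNA replication without G2 replicate 1 (0.167), G2 replicate 2 (0.0796), S replicate 1 (0.0557) or S replicate 3 (0.116).

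Between G2 and M, which asks what changes at entry into division, tags of B-type cyclin and kinesin motor motifs rose and those of the core histones, PCNA and MCM helicase fell. Tags of B-type cyclin rose 6.71-fold, from 7.74 ± 3.15 to 51.9 ± 5.77 CPM (SD, n = 3), and those of kinesin motor motifs, found in the motors of spindle and cell plate, 3.46-fold, from 4.50 ± 0.542 to 15.6 ± 3.87. Tags of alpha-tubulin and beta-tubulin rose 1.55-fold and 1.54-fold, to 5132 ± 316 and 2260 ± 145 CPM. Histone H4 tags were 7.93 times, histone H3 5.62 times, histone H2A 3.47 times and histone H2B 3.19 times as frequent in G2 as in M, while PCNA, MCM helicase and alpha-expansin, a wall-loosening protein, were 2.20, 1.88 and 1.74 times as frequent. edgeR called 14 of 27 sums, 7 up and 7 down. Its adjusted p was 3.11e-05 for B-type cyclin, 0.000744 for kinesin motor motifs, 0.0342 for alpha-tubulin and 0.0188 for beta-tubulin. For histone H4, histone H3, histone H2A and histone H2B it was 0.000488, 0.000228, 0.000941 and 0.00641. PCNA, MCM helicase and alpha-expansin had 0.00234, 0.00591 and 0.00156, and the other calls were ubiquitin, RbcS and chlorophyll a/b binding protein. B-type CDK, at 146 ± 10.7 in G2 and 164 ± 7.90 in M, was not called (0.438). The alpha-tubulin call ended without any library of G2 (0.0509, 0.111 and 0.0792 without replicates 1, 2 and 3) or M (0.0565, 0.084 and 0.0988) or S replicate 2 (0.0524). The beta-tubulin call ended without G2 replicate 2 (0.0777), G2 replicate 3 (0.0665), M replicate 3 (0.0619) or a composition factor (0.0732), and both tubulin calls without G2 replicate 3 and S replicate 3 together (0.0924 and 0.074). With every matched tag counted, linked or not, PCNA was not called (0.103; log2 change −0.43 in place of −1.14). The same count took the log2 change of B-type cyclin from 2.73 to 1.67 and that of kinesin motor motifs from 1.79 to 1.20, both still called.

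edgeR called 9781 single tags between G2 and M, 2055 higher in M and 7726 lower. CTTTCAAATGAGGAAATTGC went from 0.0228 ± 0.0395 to 4.95 ± 1.57 CPM (log2 change 6.99) and AATTTTTGCGGAAGTTACCG from 0.0114 ± 0.0197 to 3.07 ± 1.81 (7.05), both at edgeR adjusted p = 0.0024. TGTATCTGTGCTGTTAGAAT and GTGAACCTACGATAGCTTTT, at 2.47 ± 1.58 and 2.11 ± 0.511 CPM in G2, had 0 tags in the 3 M libraries, at least 39.7-fold and 33.9-fold lower against a floor of 3 counts over the phase (adjusted p = 0.00253 and 0.0024). The count was 5849 without G2 replicate 1 and 2647, 2905 and 2741 without M replicates 1, 2 and 3.

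As sets between G2 and M, core and linker histones fell (median log2 change −2.49; camera adjusted p = 6.28e-84, and 0.0451 with an estimated correlation). Of 6973 histone tags 2992 fell over all tags, and adjusted over the list alone 5161 fell and 2 rose. Tubulins and actins rose (median 0.69, camera adjusted p = 1.17e-22, and 0.0422 with an estimated correlation), with 15 of 3320 tags up over all tags and 0 adjusted over the list alone. The actin sum did not share this rise, at 964 CPM in G2 and 976 in M without a call. Mitotic cyclins and B-type CDKs rose with a median of 0.16 (camera adjusted p = 0.0182), but not with an estimated correlation (adjusted p = 0.219), nor without G2 replicate 1 (0.0888) or G2 replicate 2 (0.133), and 0 members were called either way. Cytosolic ribosomal proteins (0.355), heat shock proteins and chaperones (0.198), G1 cyclins and G1/S regulators (0.0877), DNA replication (0.9; median 0.06 although the test pointed down) and the small RNA pathway (2 AGO1 tags; 0.208) were not called, and 1 of the AGO1 tags rose when adjusted over the list alone.

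Between M and G1, which asks what changes as cells leave division, tags of mitotic and microtubule genes fell. B-type cyclin tags were 7.20 times as frequent in M (51.9 ± 5.77 CPM) as in G1 (7.21 ± 2.18; SD, n = 3), B-type CDK tags 6.09 times, kinesin motor motifs 5.19 times, beta-tubulin 6.29 times and alpha-tubulin 3.62 times. Tags of PCNA and MCM helicase rose 4.03-fold and 3.91-fold, to 69.6 ± 28.96 and 54.6 ± 0.939 CPM. Histone H4, histone H3 and histone H2A tags rose 4.74-fold, 2.67-fold and 2.10-fold, and alpha-expansin 1.61-fold. G1 replicate 1 held 2442 CPM of histone H4 tags against 623 and 653 in the other G1 libraries. edgeR called 13 of 27 sums, 6 up and 7 down. Its adjusted p was 2.51e-05 for B-type cyclin, 1.7e-07 for B-type CDK, 9.89e-05 for kinesin motor motifs, 9.24e-07 for beta-tubulin and 3.57e-05 for alpha-tubulin. Those that rose had 3.57e-05 for PCNA, 3.17e-05 for MCM helicase, 0.00282 for histone H4, 0.00744 for histone H3, 0.0188 for histone H2A and 0.00374 for alpha-expansin. RbcS and chlorophyll a/b binding protein were also called. The log2 value of histone H2B, 1.01, was not called (0.0706), but passed without G1 replicate 2 (0.0304) or 3 (0.0331). Without G1 replicate 1 the log2 change of histone H4 dropped from 2.24 to 1.29 and that of histone H3 from 1.42 to 0.68, both still called, while histone H2A was lost (0.0576), as it was without M replicate 2 (0.0655) or without G2 replicate 3 and S replicate 3 together (0.0522). With every matched tag counted, log2 changes shrank but were still called: from −2.86 to −1.74 for B-type cyclin, −2.61 to −1.89 for B-type CDK, −2.42 to −1.68 for kinesin motor motifs, 2.01 to 0.98 for PCNA and 1.97 to 1.34 for MCM helicase.

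edgeR called 2897 single tags between M and G1, 465 higher in G1 and 2432 lower. ACAGTTAGAGGCTCTGGAGG went from 0.0176 ± 0.0304 to 1.69 ± 0.769 CPM (log2 change 5.98; edgeR adjusted p = 0.00549) and CTTTTTTATCTCTGGGATGT from 0.0633 ± 0.0102 to 1.51 ± 1.01 (4.48; 0.0197). TGCTGTTGCACTGCAACCTC went from 2.43 ± 0.207 to 0.0806 ± 0.0417 CPM (−4.88; 0.00492) and ATACCAAGGAGGTGAGGCTG from 2.34 ± 0.408 to 0.0944 ± 0.0557 (−4.59; 0.00557). The count was 0 without G1 replicate 1 (11104 at an unadjusted p under 0.05), and 557 and 1303 without G1 replicates 2 and 3. It was 616, 594 and 229 without M replicates 1, 2 and 3, 4892 without G2 replicate 3 and 5396 without S replicate 3.

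As sets between M and G1, mitotic cyclins and B-type CDKs fell (median log2 change −3.07; camera adjusted p = 1.92e-53, and 0.000191 with an estimated correlation), with 27 of 55 tags down over all tags and 48 adjusted over the list alone. Tubulins and actins fell (median −2.31, camera adjusted p = 9.27e-149, and 0.000361 with an estimated correlation). Of these 3320 tags 1292 fell over all tags, and 2721 fell and 6 rose adjusted over the list alone. The actin sum did not share this fall, at 976 CPM in M and 932 in G1 without a call. The 3 A-type CDK tags that stood for G1 cyclins and G1/S regulators fell (median −3.25; 6.37e-07, and 0.0144 with an estimated correlation), 1 of them over all tags and 3 adjusted over the list alone. At the preset correlation of camera, core and linker histones (median 1.53; 1.45e-45), DNA replication (0.35; 0.018) and cytosolic ribosomal proteins (0.27; 0.000121) rose, and heat shock proteins and chaperones fell (−0.51; 6.35e-13). None of these calls held with an estimated correlation, at adjusted p = 0.136, 0.215, 0.542 and 0.146. Of histone tags 232 rose over all tags and 2347 adjusted over the list alone, and 1 DNA replication tag rose by both. Without G1 replicate 1 the calls of ribosomal proteins (0.419) and DNA replication (0.117) ended, and the small RNA pathway was not called (0.27).

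Between G1 and S, the phases before and after the start of replication in the cycle, tags of all 4 core histones rose. The comparison sets samples of these phases side by side and does not follow cells from G1 into S. Those of histone H3 rose 5.63-fold, from 1962 ± 1358 to 11039 ± 1771 CPM (SD, n = 3), histone H4 4.39-fold, histone H2A 3.67-fold and histone H2B 3.32-fold. B-type CDK tags rose 4.01-fold to 108 ± 15.3 CPM, beta-tubulin 2.60-fold, alpha-tubulin 2.25-fold and alpha-expansin 1.39-fold. PCNA, at 69.6 ± 28.96 and 80.3 ± 7.55 CPM, and MCM helicase, at 54.6 ± 0.939 and 41.7 ± 13.5, were not called (edgeR adjusted p = 0.553 and 0.182). edgeR called 11 of 27 sums, 10 up and 1 down, the latter being RbcS. Its adjusted p was 0.000228 for histone H3, 0.00374 for histone H4, 0.000737 for histone H2A and 0.00556 for histone H2B. For B-type CDK it was 9.24e-07, for beta-tubulin 0.000111, for alpha-tubulin 0.00112 and for alpha-expansin 0.0267. Chlorophyll a/b binding protein was also called. The alpha-expansin call ended under 6 of 21 alternatives. Among these were the fits without G1 replicate 3 (0.0643), S replicate 1 (0.0552), S replicate 3 (0.0874) or a composition factor (0.138). Without G1 replicate 1 the log2 changes of histone H4, histone H3, histone H2A and histone H2B went from 2.13, 2.49, 1.87 and 1.73 to 3.09, 3.23, 2.49 and 2.46, and without G1 replicate 1, G2 replicate 3 and S replicate 3 together to 3.29, 3.18, 2.55 and 2.62. That of B-type CDK went from 2.00 to 1.34 with every matched tag counted. Without G1 replicate 1, which held 103 CPM of PCNA tags, PCNA was called as higher in S (log2 change 0.60, edgeR adjusted p = 0.0136). The same fit called B-type cyclin as lower in S (edgeR adjusted p = 0.0306). Without S replicate 3 MCM helicase was called as lower in S (log2 change −0.64, edgeR adjusted p = 0.0304). With the replicate number as a block 16 sums were called. The added ones were actin (log2 change 0.35; 0.0395), ribosomal protein S23 (−0.32; 0.0252), ribosomal protein L23 (−0.46; 0.00441), ribosomal protein L40 (−0.38; 0.0107) and ribosomal protein S29 (−0.27; 0.0185).

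edgeR called 10944 single tags between G1 and S, 9962 higher in S and 982 lower. GTTGATAAGGAAGCTGCCG went from 0.0502 ± 0.0870 to 5.06 ± 5.25 CPM (log2 change 6.07; edgeR adjusted p = 0.00431) and AAATTCACCACTATTATTG from 0.168 ± 0.246 to 17.1 ± 27.3 (6.87; 0.0246), with 560 of its tags in S replicate 3 and 14 and 26 in S replicates 1 and 2. AGATCTTGGTGGTAGTAGC went from 14.1 ± 10.7 to 0.338 ± 0.0869 CPM (−5.36; 0.00357). TTAAATAGGTAGGACGGTG, at 2.93 ± 1.91 CPM in G1, had 0 tags in the 3 S libraries, at least 41.01-fold lower against a floor of 3 counts over the phase (0.00357). The count was 20791 with the replicate number as a block, 18260 higher in S and 2531 lower. Without the block it was 0 without G1 replicate 2 (30683 at an unadjusted p under 0.05) or G1 replicate 3 (30847), and 5808, 6344, 5933 and 6896 without M replicate 1, M replicate 3, S replicate 1 and S replicate 2.

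As sets between G1 and S, core and linker histones rose (median log2 change 2.13; camera adjusted p = 2.31e-85, and 0.0451 with an estimated correlation), with 3089 of 6973 tags up over all tags and 5510 adjusted over the list alone. Mitotic cyclins and B-type CDKs rose (median 2.12, camera adjusted p = 1.7e-11, and 0.0144 with an estimated correlation). Of these 55 tags 19 rose over all tags and 35 adjusted over the list alone. The sum of B-type cyclin, the only cyclin in this list, went the other way without a call, from 7.21 CPM in G1 to 4.64 in S. That of B-type CDK rose 4.01-fold. Tubulins and actins rose (median 1.27; 7.58e-24, and 0.0422 with an estimated correlation), with 386 of 3320 tags up over all tags, and 880 up and 1 down adjusted over the list alone. Cytosolic ribosomal proteins fell at the preset correlation of camera (median −0.44; 9.65e-10) and not with an estimated one (adjusted p = 0.317). Not called were the small RNA pathway (0.731), DNA replication (0.9; median 0.24 although the test pointed down), heat shock proteins and chaperones (0.27; median 0.05 although the test pointed down) and G1 cyclins and G1/S regulators (0.731).

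Phases that do not follow each other were compared by counts. edgeR called 20095 tags between S and M, 3479 higher in M and 16616 lower, and 1548 between G2 and G1, 358 higher in G1 and 1190 lower. With the replicate number as a block the G2 and G1 count was 7290, 1620 higher in G1 and 5670 lower. In the fit lacking the block it was 0 without G1 replicate 2, G1 replicate 3 or G2 replicate 2 (17688, 18118 and 23521 at an unadjusted p under 0.05). It was 707 and 588 without G2 replicates 1 and 3, 51, 146 and 51 without M replicates 1, 2 and 3, and 910, 691 and 3291 without S replicates 1, 2 and 3.

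Candidate cleavage tags, 45 in all, were found for 17 of 27 small RNA families. Only miR169, miR319, miR390, miR396 and miR403 had more of them than the highest of their own shuffles, while miR159, miR164, miR166 and miR393 had as many as the highest, 2, and the others fewer. The excess of miR319, 3 tags against at most 2, includes a tag at the site of the most frequent miR159 tag and does not hold without it. The most frequent, TCACTCCAAAGTCAGATGGC at a site of miR159, which targets GAMYB transcription factors, held 3902 tags, at 21.1 ± 9.92 CPM in S, 19.2 ± 8.30 in G2, 17.7 ± 4.14 in M and 18.5 ± 6.93 in G1 (SD, n = 3). GTGAATCTAATGGGATGTCA, at a site of miR403, the miRNA of AGO2, stood at 5.50, 5.83, 5.99 and 6.60 CPM in the same order. CCTGGTCCGGATTCCATTGG of miR166, the regulator of class III homeodomain-leucine zipper genes, stood at 4.44, 5.34, 2.93 and 2.63 CPM. TCCCTTTGGATGTCGTCCTG of miR393, which targets auxin receptors, stood at 4.32, 3.02, 3.38 and 3.75 CPM, TGGGAACATAAGTGACTATT of miR398, for copper superoxide dismutases, at 3.01, 2.29, 1.02 and 1.74, and TCAGGATTCTTAACTCCGGC of miR172, for AP2-type factors, at 1.73, 1.24, 2.01 and 1.36. Shuffled sequences gave 7.39 cleavage tags on average and 95 at most, and 2 of 100 shuffles gave at least 45. At a penalty of at most 3 there were 31, against 0.900 on average and 5 at most.

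Among the most frequent cleavage tags of other families were TCTTCTGTCAAATAAATCTT for miR156 (236 tags over the 12 libraries), AGAATGCCAAATATATGGTG for miR394 (128), AGCTGTGGAAGTAGATGATG for miR396 (103), TCCTTGGCTAGCGTTAAGGC for miR169 (76), and CACTTAATGATTTTGACAGG for miR397 (76). Others were TTCACTCCAAAGTCAGATGG for miR319 (53), TTTTGAGCTTGTGTTATTTT for miR390 (42), AGGTCAAGAAAATTTAGGTC for tasiR-ARF (34), GGCAGCTTGTATTTGTAGAC for miR167 (31) and TGCTTCTCCAATTTCGTTAG for miR164 (30). The miR319 tag starts 1 nt before the most frequent miR159 tag, at the same site. No cleavage tag was found for miR168, the miRNA of AGO1, nor for miR160, miR162, miR171, miR395, miR399, miR408, miR482, miR828 or miR858. Cleavage at their sites was not detectable at this depth with the sequences and limits used, which does not show that it is absent. For miR171, a sequence of the miR171b type gave cleavage tags with 8596 and 4050 counts, described below.

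**Figure D3:**
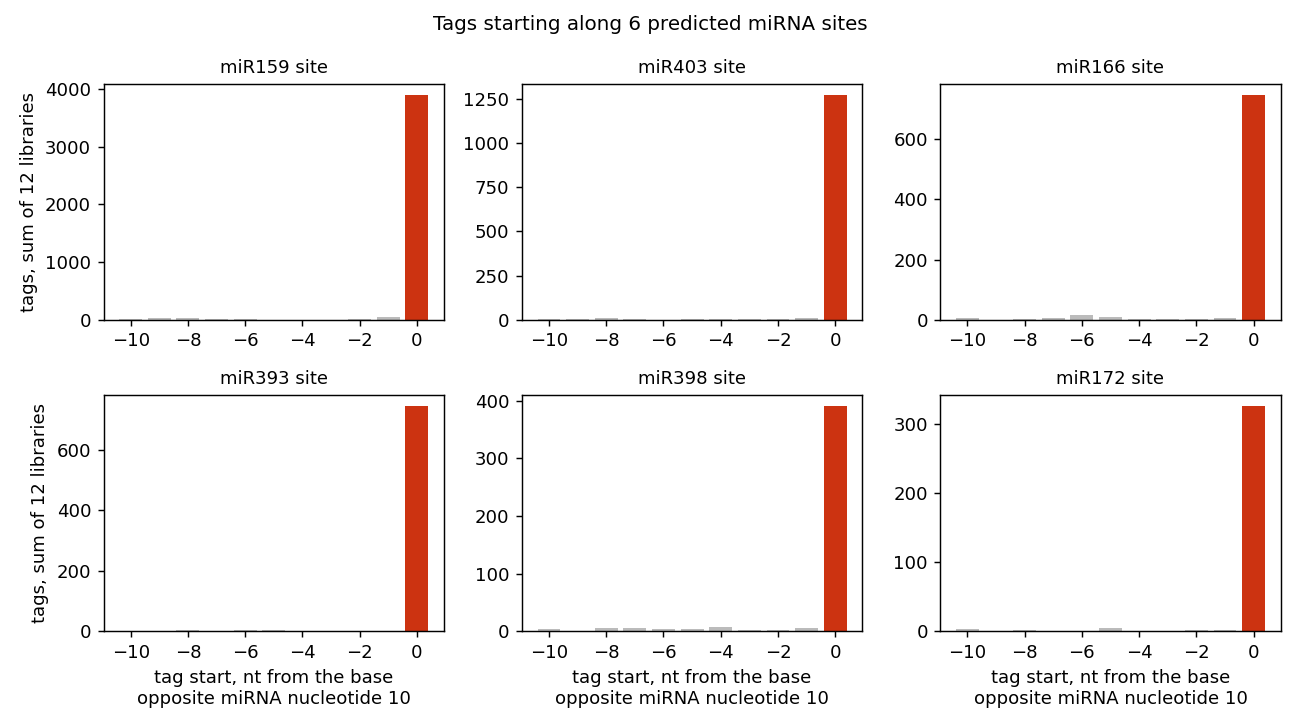
Tags over the 12 libraries by the position of their first base, from 10 nt before the cut to the cut opposite miRNA nucleotide 10, at the most frequent sites of 6 families (bars, summed tags). The last bar is the highest in each panel by selection, since a cleavage tag had to be the most frequent of the possible starts. That it is the highest is therefore no separate evidence of cleavage. The last bar of miR159 holds 3902 tags.

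None of the 45 cleavage tags passed the test between phases in edgeR. Over the 4 phases the lowest adjusted p was 0.136, with 2 tags at an unadjusted p under 0.05. The lowest adjusted p from S to G2, G2 to M, M to G1 and G1 to S were 0.92, 0.0878, 0.652 and 0.809, with 0, 2, 2 and 5 tags at an unadjusted p under 0.05. DESeq2 called 0 in each of these tests. Over the 4 phases the lowest value was shared by GTGAATCTAATGGCATTTCA of miR403, at 2.97, 2.40, 0.708 and 1.11 CPM in S, G2, M and G1, and TTCAGTCCAAAGTGAAGTGA of miR319. The latter also had the lowest value from G2 to M, with 0 tags in the 3 G2 libraries and 1, 10 and 6 in those of M. Summed per family, the 17 families had exact permutation p of at least 0.0473 (miR164), and none passed after adjustment (0.804), while without M replicate 3 miR394 did (adjusted p = 0.0364). Over the phases 1 cleavage tag was called without G2 replicate 1, M replicate 1 or S replicate 2, and from G2 to M 1 was called without M replicate 1, S replicate 2 or S replicate 3.

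The bases of codons at which tags started showed no phase that stood apart. First bases took 32.2% ± 1.38 of the 5935008 tags in S, 32.2% ± 1.18 in G2 and 32.8% ± 0.133 in M (SD, n = 3), with an exact permutation p of 0.642 over the 4 phases, and second bases reached p = 0.0499 (adjusted p = 0.1498). Terminating ribosomes leave ends 16 and 17 nt upstream of stop codons in plant degradomes. Tags there were less frequent than those 20 to 50 nt upstream, with log2 ratios of −0.62, −0.76, −0.73 and −0.42 in S, G2, M and G1. The exact permutation p over the phases was 0.737. These starts lie at the end of the matched sequence, where a tag can be linked only to tags upstream of it. The matching itself thus lowers their number, so the ratios do not show whether ribosomes left ends there. Tags of 5.8S rRNA made up 0.706% ± 0.0801 of the libraries in S, 0.598% ± 0.373 in G2, 1.15% ± 0.144 in M and 0.755% in G1 (exact permutation p = 0.0629, adjusted p = 0.315), and the other 4 shares had adjusted p = 0.720. Without G2 replicate 3 the 5.8S rRNA share passed (adjusted p = 0.0130).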

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

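The search behind this part was chosen only after the start profiles of other sites had been seen. A sequence of the miR171b type, a variant of miR171 that differs from it by its register on the target, was not among the 27 families searched, and with it 2 cleavage tags were found that the comparison of families had left out. CGCGGCTCAATCACCAGCTC held 8596 tags over the 12 libraries, more than the most frequent miR159 tag, and CGCGGCTCAATCAACAGCTC held 4050. Shuffled sequences gave 0.130 cleavage tags on average and 4 at most, so finding 2 does not by itself exceed the shuffles, and how many tags the shuffled sites held was not compared. Known targets of miR171 are GRAS-domain genes of the HAM and SCL6 type, which keep meristem cells undifferentiated. The first tag stood at 73.3 ± 40.4 CPM in S, 41.02 ± 26.7 in G2, 32.6 ± 6.41 in M and 34.0 ± 10.6 in G1 (SD, n = 3), and the other at 18.9, 16.3, 13.5 and 31.1 CPM. No test of these tags between phases is reported here, and no explanation was tested.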

How the results depend on the processing

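Settings chosen only after the data had been seen were the looser filter, no composition factor, joining by 18 nt, the other ways of matching tags to proteins and choosing proteins, RLE factors for the sums and cleavage tags, DESeq2 for the sums, and leaving out 2 libraries (G2 replicate 3 and S replicate 3) or 3 (also G1 replicate 1). Of 47 called changes of protein sums between successive phases, 32 held under all 21 alternatives, 15 were lost under at least 1 and 0 reversed; of 16 sums called over the phases 14 held, and 5 of the 11 not called passed under some alternative. Numbers of tags called moved most, and unless stated the cause was not tested.

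Over all 4 phases the replicate numbers marked a shared structure, though not every pair with the same number met the limit of 0.1. Of 18 such pairs 14 had a correlation of deviations above 0.1, and all 18 ranged from −0.0488 to 0.729. Within S, G2 and G1 every such pair met the limit. The median was 0.261 for the same number and −0.137 for other numbers, and 11 of 12 libraries correlated best with their own number. The main fit has no block, so its calls do not take out this structure. With the replicate block, tags called were 3950 from S to G2, 14968 from G2 to M, 6532 from M to G1, 20791 from G1 to S and 7290 between G2 and G1, and cleavage tags 2 over the phases and 2 from G2 to M. Among S, G2 and G1 it changed no other call than those of the sums named beside their results.

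From S to G2, tags called were 32 without a composition factor, 10 with the stricter filter (fewer tags tested), 544 with the looser one, 588 joined by 18 nt, 1707 in DESeq2, 36 without the 2 libraries and 1528 without the 3. From M to G1 they were 1675, 4896, 4722 and 4755 with the stricter filter, looser filter, joining and DESeq2, and 8894 without the 2 libraries. From G2 to M they were 17243 and 20233 without the 2 and the 3, and from G1 to S 18281 and 21318. Between G2 and G1 they were 3625 in DESeq2, 5584 without the 2 and 11154 without the 3, between S and M 13333 and 35565 with the stricter and looser filter, and over the phases 37489 with the looser filter, 33033 without the 2 and 32951 without the 3. Without the 2 libraries 5 protein sums were called from S to G2. Cleavage tags called were 2 over the phases and 1 from G2 to M without the 3, 1 from G2 to M without the 2, and 1 with starts above the median. Lists called with an estimated correlation were 2 from S to G2 and 3 from M to G1. Cleavage tags found were 120 at a penalty of at most 5 (39.7 in shuffles) and 20 at 50 tags (2.32).

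Leaving out each library in turn gave 0 to 225 tags from S to G2, 2647 to 12859 from G2 to M, 0 to 5396 from M to G1, 0 to 13593 from G1 to S, 15154 to 26953 between S and M, 0 to 3291 between G2 and G1 and 13999 to 27225 over the phases; with fewer libraries the filter kept 220492 to 242931 tags in place of 183819. Protein sums called were 15 to 17 over the phases and 6 to 12, 11 to 15, 12 to 15 and 10 to 13 for the steps from S to G2, M, G1 and S. Cleavage tags were 0 to 1 over the phases and from G2 to M and 0 to 0 for the other steps, and lists 5 to 7, 2 to 4, 5 to 7 and 4 to 5. Lowest adjusted exact permutation p were 0.0364 to 0.987 for families, 0.0754 to 0.313 for codon bases, 0.267 to 0.917 for stop codons and 0.0130 to 0.741 for library shares. Among sequences 63.0% occurred in 1 library, and 2-fold changes of single tags were not recovered in a simulation that did not vary depth. Not run for lack of transcripts were the alternatives on tags of several genes and exon junctions, and for size the fit with no filter.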

Other observations

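The tests on G1 replicate 1, that on single-base variants of frequent tags, and the proteins read from the tags were chosen only after results had been seen; the other splits of the samples, the tests on the S and G2 count and that on variants with 3 changed bases were set before their own results.

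In cells grown in the dark, tags that can encode photosynthesis proteins were scarce but differed between phases; both proteins here fall short of the earlier background rule, on tag totals. Tags of chlorophyll a/b binding protein, the antenna of the photosystems, went from 12.6 ± 3.97 CPM in S to 3.31 ± 0.758 in G2, 14.5 ± 1.85 in M and 6.46 ± 0.779 in G1 (SD, n = 3). Each step was called by edgeR, with log2 changes of −1.91 from S to G2 (adjusted p = 8.76e-05), 2.11 from G2 to M (3.57e-05), −1.17 from M to G1 (0.00218) and 0.97 from G1 to S (0.00641). With every matched tag counted, linked or not, the changes of chlorophyll a/b binding protein from S to G2 and G2 to M were −1.31 and 1.45, both still called. Tags of RbcS, the small subunit of Rubisco, stood at 0.371, 0.375, 2.16 and 0.978 CPM in S, G2, M and G1, with calls from G2 to M (log2 change 2.34; adjusted p = 0.000353), M to G1 (−1.14; 0.0149) and G1 to S (−1.35; 0.0267). Without G2 replicate 1 the first of these was 3.01. The RbcS calls were lost when every matched tag was counted (log2 changes of 0.28, −0.25 and −0.37; adjusted p of 0.464, 0.531 and 0.328), and that from M to G1 also without M replicate 1 (0.069). The call from G1 to S ended without S replicate 1, 2 or 3 (0.0562, 0.0571 and 0.0795).

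Tags of ubiquitin fell from 2542 ± 162 CPM in S to 1523 ± 355 in G2 (log2 change −0.74; edgeR adjusted p = 0.00502) and rose to 2212 ± 58.5 in M (0.54; 0.0267). The rise was not called under 7 of 21 alternatives. Among these were the fits without G2 replicate 2 (0.107), G2 replicate 3 (0.106), M replicate 1 (0.0728), M replicate 2 (0.0611), M replicate 3 (0.0655) or a composition factor (0.118). Tags of HSP70, a stress-inducible chaperone, stood at 1664 ± 528, 2419 ± 625, 2182 ± 324 and 1585 ± 180 CPM in S, G2, M and G1. They were not called over the phases (edgeR adjusted p = 0.128), but passed under 6 of 21 alternatives. Among these were leaving out G2 replicate 1 (0.0448) or S replicate 3 (0.0214).

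Histone tags in G1 replicate 1 were 2.61 to 3.83 times their mean in the other 2 G1 libraries and PCNA tags 1.94 times, while those of MCM helicase were 1.00 times and those of alpha-tubulin 0.525 times. S cells mixed into that sample would put alpha-tubulin tags between the G1 and S libraries, but they stood at 884 CPM, below the lowest other G1 or S library (1680), while PCNA tags (103) lay above the highest S library (88.2). A library of another phase under this label is argued against by B-type CDK tags at 27.3 CPM, where the lowest S, G2 or M library had 97.6. An effect shared by replicate 1 of each phase cannot be told apart, since the mean log2 excess of histone tags in replicate 1 was 1.62 in G1 and 0.52, 0.62 and 0.23 in S, G2 and M, and the difference from the highest, 0.9994, lay just inside the limit of 1 set for excluding it. A sample taken nearer to the start of S may also explain the pattern, and this was not tested.

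Few tags were called between S and G2. Joining tags by their first 18 nt raised the count from 66 to 588, which is consistent with differences in tag length between libraries (4.24% to 15.8% of 19 nt) as a candidate explanation, although joining also puts more counts into each tag. The spread added by G2 replicate 3 and S replicate 3 cannot be told apart: the count was 36 without both, 0 without G2 replicate 3 and 37 without S replicate 3. It had been set that no gain would exclude this, but that bound was wrong, since leaving out a library of the phases not compared also lowered the count (8, 0 and 0 for G1 replicates 1, 2 and 3, and 0 for each M library). With the replicate number as a block, which takes out spread shared by libraries of a number, the count was 3950.

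Tags that can encode GFP, the fusion partner of AGO1, were not above background, with linked tags for 27 of 234 peptides against a median of 22.5 and at most 35 in 20 shuffles. If only exact matches to tobacco sequence had been deposited, few single-base variants of frequent tags should be there, but all 360 possible ones of the 6 most frequent tags were. For a limit of up to 2 mismatches, it had been set that variants with 3 changed bases would be no more frequent than random 20-mers. They were at least 44.2 times as frequent. This cannot decide the question, since such a variant may match another, related tobacco sequence within 2 mismatches. A limit of this kind stays open. A low level of the transgene's transcript, or a fusion sequence that differs from the protein searched, may account for the lack of GFP tags above background. Neither was tested.

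Other splits of the libraries were counted on 10000 seeded tags, the 27 sums and the 8 lists. The lists were here compared with the seeded tags and the tags of the other lists in place of all 183819, so their counts differ from the 7, 3, 7 and 4 called for the steps from S to G2, M, G1 and S. Over the 4 phases, 1 of 100 groupings, the real one, called as many tags (1082 against at most 598 in the others). For protein sums 1 of 100 did (16 against at most 8). The regroupings were drawn without regard to the replicate numbers, so these shares make chance unlikely but do not exclude it. For miRNA cleavage tags the real grouping called 0, and 3 was the highest. That 100 of 100 groupings called at least 0 was fixed in advance and says nothing about chance. With 3 libraries against 3 the 10 splits never give a share under 0.1. From S to G2 the real split called 7 tags, 9 sums and 6 lists and the highest other 495, 2 and 6, as many being reached by 2, 1 and 2 of the 10 splits. The split with 495 tags set G2 replicate 1 and S replicates 1 and 2 against G2 replicates 2 and 3 and S replicate 3, which points to a structure of the samples, since it keeps the libraries numbered 1 together and those numbered 3 together. The other splits of S and G2 that, like the real one, part all 3 numbers called 0 tags, 0 sums and at most 6 lists. From G2 to M the real split called 551 tags, 14 sums and 5 lists and the highest other 0, 0 and 6 (1, 1 and 4 splits). From M to G1 these were 171, 13 and 6 against 0, 0 and 6 (1, 1 and 2 splits), and from G1 to S 541, 11 and 5 against 0, 1 and 6 (1, 1 and 4 splits), or 0, 0 and 5 among those that part all 3 numbers. Between S and M the real split called 1067 tags and the highest other 0, and between G2 and G1 103 and 2 (1 split in each).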
